A study of Bos taurus with 6 samples.

How the data were processed

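Total RNA from longissimus dorsi samples of Angus and Chinese Simmental cattle, 3 libraries per breed, was made into sequencing libraries from 1 µg of RNA with an Illumina mRNA kit after freezing in liquid nitrogen and Trizol extraction, per the labels' protocols. Samples were grouped by the breed in their titles, and the replicate numbers come from the same titles. Reads were aligned with HISAT2 and the genome build was ARS-UCD1.2, per the submitters' processing notes. The counting tool, the strand setting, the annotation and the tool for the comparison are not given in the sources used here.

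The deposited table held, per the file headers, whole-number counts per gene and library, FPKM values per gene and library, group means of scaled counts (a normalized signal), and the authors' log2 fold change, p-value and adjusted p. Names in the file headers matched sample titles, and 0 per-sample columns were left unused. The table had 2040 gene rows and 1 blank row, which was left out. It held only genes that the authors had selected, so no genome-wide test could be made. If the deposited adjusted p follow the Benjamini-Hochberg rule, the authors tested about 20345 genes, of which about 3346 had p at or below the largest listed p. The authors' deposited group means equal counts divided by size factors, and the size factors solved from them left relative residuals below 5e-10 (largest 4.72e-10 and 4.85e-10 for the 2 breeds). They were 1.17, 0.801 and 1.02 for Angus replicates 1 to 3 and 0.951, 1.09 and 1.03 for Chinese Simmental replicates 1 to 3. Ratios of deposited counts to deposited FPKM gave relative library totals of 1.04, 0.821 and 1.06 and of 0.829, 1.09 and 1.22. For 1500 genes with at least 50 counts in each library the median SD of log2(count/FPKM) over libraries was 0.0666, and 11 genes had an SD above 1. FPKM gave the same direction as counts for 2034 of 2040 genes.

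The 2040 names covered 1975 distinct sets of counts, and 114 names shared their counts with another name at 49 loci, so each such locus was used once in gene lists. Symbols matched the RefSeq gene table of assembly ARS-UCD2.0 for 1749 names and as synonyms for 24 more. Of all 2040 names, 222 were assembled transcripts without a symbol, 165 were provisional LOC names, most of them among the matches, and 3 were septin names turned into dates. Since the table's assembly differs from the files' build, no coordinates are printed. Reads of paralogs and overlapping genes could be split by the counting and their levels are uncertain.

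Counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest, filterByExpr with a minimum count of 10, Benjamini-Hochberg adjusted p under 0.05), with breed as the only term over all 6 libraries. The design, the naming rule for genes and 35 gene lists were fixed before the data were examined, and that design named TMM factors. As the table held only selected genes, most of them higher in Chinese Simmental, factors computed over them would centre their fold changes and so move them toward Angus. The authors' size factors were used in their place. That change was made after seeing the data, and TMM, the planned scaling, was kept as an alternative. The standard error of a log2 fold change is its size divided by the square root of F. Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2, at a preset correlation of 0.01. Of the 35 fixed lists, 10 had at least 5 listed loci. A further 7 lists (B cell, T cell, natural killer and cytotoxic, monocyte, neutrophil, platelet and muscle fibre genes) were chosen once the data had been seen, of which 5 had at least 5 listed loci. Groups of 3 against 3 cannot give an exact permutation p under 0.1, so none was run for single genes.

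The naming rule took the 10 largest differences in each direction among genes past the threshold with a symbol, non-overlapping breeds and a mean FPKM of at least 1, then up to 4 genes per list with the smallest p, then 12 fixed genes, and it named 92 listed genes. A few items that the rule would name are not reported here. A fold against a breed with no reads was computed against a floor of 3 counts over that breed's 3 libraries, which covers counting error only. BBS5, NKG7, GZMA and the genes given under the added lists and annotation terms were named after their values were seen.

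Before the test was run on the real counts it was tested on simulated data for Angus against Chinese Simmental, with 1989 genes drawn from the real means and library sizes and 200 of them set to change. It called 0.168% of 1781 unchanged genes, 6.12% of genes at an absolute log2 fold change of 1 and 54% of those at 2. Camera gave a p of 8.12e-07 for a shifted set and a p under 0.05 for 0 of 50 random sets. The simulated genes were drawn independently and changed evenly in both directions. Neither test was therefore tried on correlated genes or on genes that mostly change toward 1 breed. No pair of libraries of the same breed agreed within sampling noise, with chi-square per degree of freedom of 304 or more.

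Replicate numbers are shared by both breeds. The correlations of deviations from the group means for same-numbered libraries were 0.265, 0.148 and 0.240. All were over 0.1, which met a rule fixed in advance for treating the numbers as pairs. The main test still had breed as its only term, and the pairing entered only through the replicate block, an alternative. The pairing comes from these values and from no label, and 1 pair with different numbers (Angus replicate 3 and Chinese Simmental replicate 2) reached 0.219. Alternatives were RLE, upper quartile and TMM factors over the listed genes, totals implied by FPKM, no filter and a minimum count of 100, the replicate number as a block, a robust fit, leaving out mitochondrial and the 10 most abundant genes, leaving out each library, limma-trend, limma on log2(FPKM + 1) and log2(FPKM + 0.1), DESeq2 1.42.0 with the authors' size factors, and for lists an estimated correlation, fry and Fisher's exact test of direction.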

Results

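RNA sequencing compared longissimus dorsi, the long muscle of the back from which rib steaks are cut, between Angus, a beef breed, and Chinese Simmental cattle. The labels place the samples at ribs 12 and 13 of cattle aged 18 months, and the study's title names intramuscular fat content as its subject. Each breed had 3 libraries. The labels do not say whether the 3 samples of a breed came from separate animals, so p-values measure the spread between these samples only. The deposited table held 2040 named or numbered genes with counts and FPKM for all 6 libraries. Every gene in it had passed the authors' own selection, since the smallest absolute deposited log2 fold change was 1.00 and the largest deposited adjusted p in the authors' deposited table was 0.0492. Counts over these listed genes summed to 14907696, 12010803 and 15699184 in Angus replicates 1 to 3 and to 12799174, 22178270 and 28883725 in Chinese Simmental replicates 1 to 3. These sums cover only the listed genes, so the sequencing depth of each library is unknown here. A gene outside the table was not analysed here, and nothing is said of its level. Values below are counts divided by the authors' size factors, as mean ± SD over the 3 libraries of a breed, and log2 fold changes are Angus minus Chinese Simmental ± standard error.

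Among the listed genes, all 5 found of the fixed MHC class II list, which counts the activator CIITA, were higher in Angus. So were the B cell markers CD79A, CD79B and MS4A1, and all 10 listed myeloid markers were higher in Chinese Simmental. Of the 10 listed loci annotated to the MHC class II protein complex, 8 were higher in Angus and 2 in Chinese Simmental. Against the other listed genes, limma's camera gave adjusted p = 0.00417 for MHC class II, adjusted p = 0.0211 for lymphocyte markers and adjusted p = 0.0211 for myeloid markers, and with an estimated correlation adjusted p = 0.226, 0.618 and 0.740. Of the 10 ways to split the libraries into 3 and 3, 5, the real one included, gave at least 3 lists past the threshold. CD79B, a chain of the B cell receptor complex, was 5.28-fold higher in Angus, at 55887 ± 9123 against 10582 ± 4028. CD163, a scavenger receptor of macrophages and monocytes, was 17.8-fold higher in Chinese Simmental, at 11535 ± 1746 against 647 ± 280. Of the 2040 listed genes, 509 were higher in Angus and 1531 (75.0%) were higher in Chinese Simmental. In the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 1989 genes passed the count filter, of which 495 were past the threshold as higher in Angus and 1492 as higher in Chinese Simmental. Because the authors chose these genes on the same libraries, these counts describe the selected genes and are not independent evidence of a difference. These genes were chosen for differing between these libraries, so the separation of the breeds in the values that follow was set by that choice. The breeds did not overlap for 1842 listed genes (90.3%), where chance alone gives 10% for unselected genes in 3 against 3 libraries. The Spearman correlation of log2 counts over these genes was 0.938 to 0.976 within breeds and 0.759 to 0.893 between breeds. The first principal component held 79.7% of the variance, and the second held 9.22% and set Chinese Simmental replicate 1 apart at 34.6. With TMM, RLE or upper quartile factors computed over the listed genes in place of the authors' size factors, log2 fold changes moved toward Angus by a median of 1.36, 1.35 and 1.32, and the calls became 503 and 256, 503 and 263, and 503 and 282. In what follows, under every scaling refers to the direction alone, and 26, 26 and 28 of the 92 named genes lost their call with these factors. Since these factors moved fold changes toward Angus, they put only the direction of genes higher in Chinese Simmental to the test. Without Angus replicate 2 the calls fell to 291 genes higher in Angus and 1059 higher in Chinese Simmental.

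Among annotated genes with non-overlapping breeds, the largest differences toward Angus were in DNER, a transmembrane ligand of Notch, ZSCAN23, a zinc finger gene, and NTNG1, a netrin-G protein of axon guidance. These genes had no read in any Chinese Simmental library and stood at 261 ± 32.8, 41.3 ± 3.40 and 26.5 ± 8.63 in Angus, which is at least 268-fold, 42.3-fold and 27.1-fold higher against a floor of 3 counts over the group. SCN3A, a voltage-gated sodium channel subunit, was 12.1-fold higher in Angus at 2080 ± 304 against 172 ± 148. CYB5R2, a cytochrome b5 reductase, was 10.9-fold higher at 613 ± 89.5 against 56.4 ± 26.6, COL26A1, a collagen gene, 14.0-fold higher at 363 ± 72.8 against 26.0 ± 23.3, and GRB7, a signalling adaptor, 9.02-fold higher at 1931 ± 1160 against 214 ± 125. Mean FPKM in Angus and Chinese Simmental was 1635 and 129 for SCN3A, but 19.6 and 1.94 for CYB5R2. The FPKM of SCN3A is out of proportion to its counts, so whether they cover its full transcript is unknown here. BRDT, ATP12A and FOXO6 completed the genes with the largest differences toward Angus, with log2 fold changes of 3.99 ± 1.07, 3.31 ± 0.87 and 3.90 ± 0.91. FOXO6, a forkhead transcription factor, ranged from 38.4 to 423.7 in Angus, and its log2 fold change was 2.43 without Angus replicate 1. BRDT was at 22.0 ± 5.54 against 1.22 ± 2.12, had reads in only 1 Chinese Simmental library, replicate 2, and without that library was at least 14.5-fold higher in Angus against a floor of 3 counts over the other 2. Leaving out 1 library also moved the log2 fold changes of SCN3A to 4.57 (without Chinese Simmental replicate 1), COL26A1 to 4.44 (without Chinese Simmental replicate 2) and ATP12A to 2.50 (without Angus replicate 1). All of these genes were past the threshold in the edgeR quasi-likelihood test, with Benjamini-Hochberg adjusted p between 0.00217 and 0.0105, and all were higher in 3 of 3 Angus libraries than in any Chinese Simmental library. The naming rule required both, and the adjustment ran over the selected genes only. In the authors' deposited table the largest adjusted p among these genes was 0.0300, for BRDT.

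Of the genes with the largest differences toward Chinese Simmental, KCTD19 had no read in Angus and stood at 21.7 ± 1.55 in Chinese Simmental, at least 21.6-fold higher. G0S2, an inhibitor of adipose triglyceride lipase, was 104-fold higher in Chinese Simmental, at 1803 ± 1797 against 17.3 ± 12.8, with Chinese Simmental replicate 1 at 58.9 and the other libraries of that breed at 1702 and 3648. PTX3, a soluble pattern recognition receptor, was 55.1-fold higher at 5510 ± 4570 against 100.01 ± 147, and ALPL, a phosphatase abundant in neutrophils, 46.4-fold higher at 12772 ± 8910 against 275 ± 211. NLRC4, an inflammasome sensor, was 28.4-fold higher at 1722 ± 1187 against 60.7 ± 21.3, and SEMA3C, a secreted semaphorin, 43.5-fold higher at 207 ± 95.8 against 4.76 ± 2.18. THY1, ADGRG3, BRB and SERPINB4 were 43.8-fold, 27.8-fold, 30.3-fold and 28.6-fold higher. SERPINB4 stood at 8184 in Chinese Simmental replicate 3 and at 696 and 1263 in the others, and its log2 fold change went from -4.84 to -3.05 without that library and to -6.85 without Angus replicate 3. THY1 stood at 46.3, 252 and 1071.9 in Chinese Simmental replicates 1 to 3, and its log2 fold change went from -5.48 to -3.86 without Chinese Simmental replicate 3 and to -6.32 without Angus replicate 2. Those of G0S2 and ADGRG3 became -5.64 and -4.07 without Chinese Simmental replicate 3 (from -6.67 and -4.80). That of NLRC4 became -4.17 without Chinese Simmental replicate 1 (from -4.82). Those of PTX3, ALPL and ADGRG3 became -8.51, -6.19 and -5.91 without Angus replicate 3 (from -5.78, -5.54 and -4.80). Adjusted p-values for these genes in the edgeR quasi-likelihood test ran from 0.00217 to 0.00972, with every Chinese Simmental library above every Angus library. The naming rule required both, and the adjustment ran over the selected genes only. In the authors' deposited table the largest adjusted p among these genes was 0.0319, for PTX3.

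**Figure D1:**
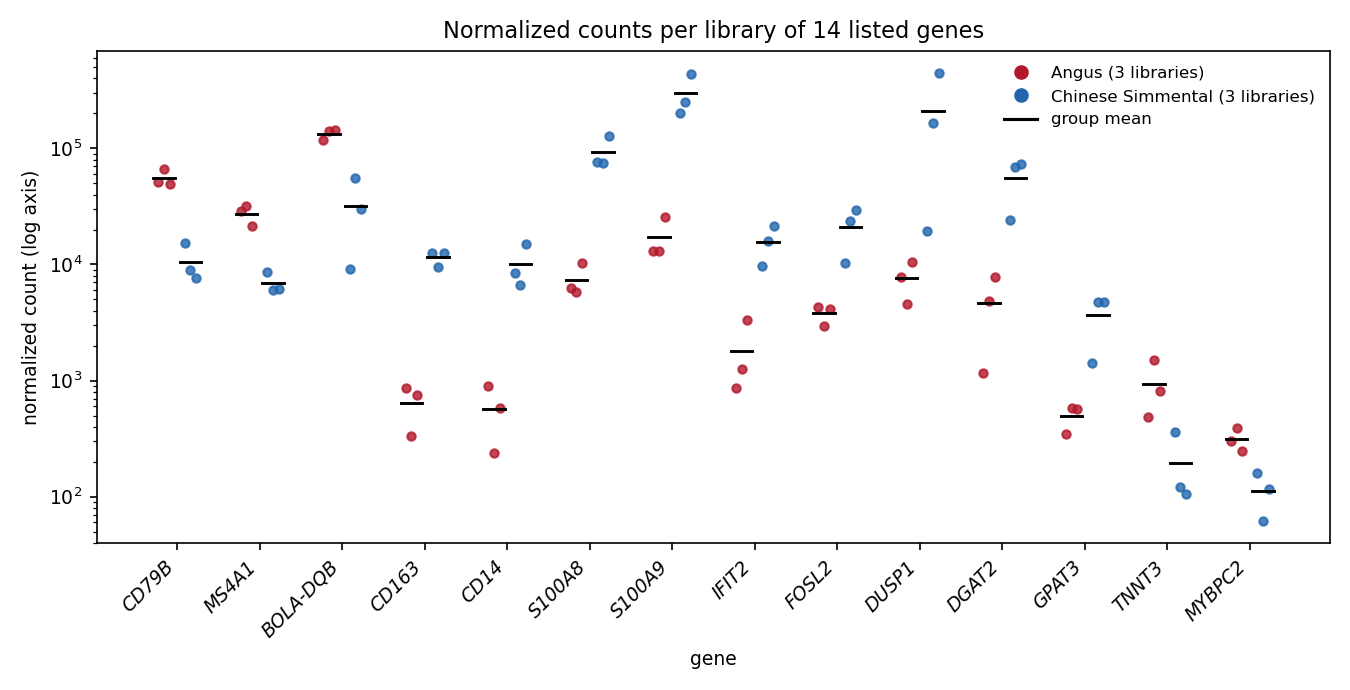
Normalized counts, on a log axis, of 14 listed genes in each of the 3 Angus (red) and 3 Chinese Simmental (blue) libraries, with the black bar at the group mean. CD79B, MS4A1, BOLA-DQB, TNNT3 and MYBPC2 lie higher in Angus and the other 9 genes lie higher in Chinese Simmental, and DUSP1 spans 19586 to 444712 within Chinese Simmental.

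Antigen presentation and B cell genes were higher in Angus. All 5 listed loci of the 12 genes fixed for MHC class II were higher in Angus, among them BOLA-DQB at 134139 ± 14992 against 31592 ± 23422 (4.25-fold), BOLA-DOA at 15476 ± 3701 against 5154 ± 2027 (3.003-fold) and BOLA-DOB at 17462 ± 6363 against 5836 ± 1719 (2.99-fold). BOLA-DQB shares its counts with a second listed name, and reads of this polymorphic family can be split between copies, so its level is uncertain, and its log2 fold change went from 2.09 to 2.78 without Chinese Simmental replicate 2. CIITA, the master activator of MHC class II transcription, was 2.68-fold higher, and its call was lost without Angus replicate 2, Chinese Simmental replicate 2 or Chinese Simmental replicate 3, with log2 fold changes from 1.19 to 1.21. Among lymphocyte markers, the B cell genes CD79A, CD79B and MS4A1 were higher in Angus, with CD79A 3.38-fold at 65888 ± 13070 against 19476 ± 4759 and MS4A1 (CD20) 3.95-fold at 27337 ± 5161 against 6912 ± 1434. NKG7 and GZMA of cytotoxic cells were higher in Chinese Simmental at log2 fold changes of -1.72 ± 0.46 and -1.42 ± 0.50, and the call for GZMA was lost without Angus replicate 3 or Chinese Simmental replicate 2, at -1.17 and -0.87.

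Myeloid genes were higher in Chinese Simmental. Of 18 macrophage and myeloid markers, 10 were listed and all 10 were higher in Chinese Simmental under every scaling. S100A9 and S100A8, the calprotectin chains of neutrophils and monocytes, were 17.2-fold and 12.6-fold higher, at 297135 ± 125882 against 17267 ± 7353 and 93383 ± 30605 against 7416 ± 2500. CD14, the lipopolysaccharide co-receptor, was 17.5-fold higher at 10010 ± 4318 against 573 ± 331. The 9 listed loci of 23 interferon response genes were also higher in Chinese Simmental, 1 of them changed direction with factors computed over the listed genes, and the list was not past the threshold against the other listed genes (adjusted p = 0.199 by limma's camera). ISG20, an antiviral exonuclease, was 11.0-fold higher at 18450 ± 8782 against 1673 ± 1331, and IFIT2 8.61-fold at 15623 ± 5827 against 1814 ± 1307. IFIT3, which shares its counts with another listed name, was 6.25-fold higher and IFIT5 2.95-fold. Without Angus replicate 3 the log2 fold changes of ISG20, IFIT2 and IFIT3 went from -3.46, -3.11 and -2.64 to -4.32, -3.87 and -3.33.

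The medians of the listed B cell genes and myeloid markers lay above that of the listed sarcomere genes in all 6 libraries labelled longissimus dorsi. The median over the 18 listed B cell loci, of a list chosen after the results were seen, was 12568 to 16626 normalized counts in Angus libraries and 3228 to 5378 in Chinese Simmental libraries, and that over the 10 myeloid markers 3180 to 7304 and 30002 to 41942. Over the 4 listed genes of the sarcomere lists the median was 392 to 691 in Angus libraries and 258 to 417 in Chinese Simmental libraries. These were 3 of 15 fast and 1 of 15 slow fibre genes, all selected by the authors for differing between breeds. The levels of the unlisted sarcomere genes are unknown here.

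**Figure D2:**
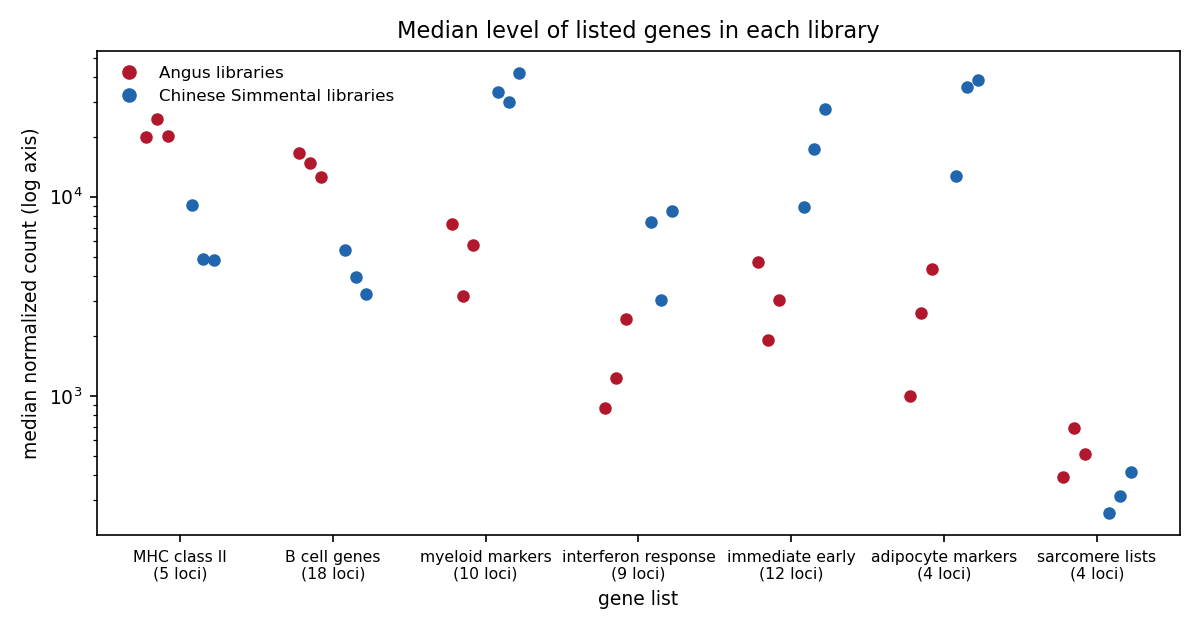
Median normalized count, on a log axis, over the listed loci of 7 groups of genes in each Angus (red) and Chinese Simmental (blue) library. The 18 B cell loci sit at 12568 to 16626 in Angus, the 10 myeloid markers at 30002 or more in Chinese Simmental, and the 4 listed sarcomere genes at 691 or less in all 6 libraries. Most genes of the sarcomere lists were not listed, and their levels are unknown here.

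Of 23 immediate early genes, which respond within minutes to stimulation, 12 were listed and past the threshold, 11 of them higher in Chinese Simmental. The 10 listed myeloid markers were also higher there (median log2 fold change -3.28). Factors computed over the listed genes turned 1 of the 11. The list was not past the threshold against the other listed genes (adjusted p = 0.346 by limma's camera). DUSP1, a phosphatase of MAP kinases, was 27.6-fold higher at 209468 ± 216163 against 7581 ± 2939, with Chinese Simmental replicate 1 at 19586, replicate 2 at 164106 and replicate 3 at 444712, and its log2 fold change went from -4.79 to -3.60 without replicate 3. FOSL2 was 5.57-fold higher at 21174 ± 9753 against 3800 ± 742, and ATF3 6.16-fold at 1441 ± 354 against 234 ± 61.6. EGR3 went the other way and was 5.39-fold higher in Angus at 538 ± 259 against 99.9 ± 35.4. Among 3 listed of 23 heat shock and unfolded protein genes, the small chaperone HSPB8 was 8.88-fold higher in Angus, and its co-chaperone BAG3 was 2.55-fold higher in Chinese Simmental. DNAJB4 was higher in Angus at 1.17 ± 0.47, a call lost when any library but Angus replicate 1 was left out, with values from 0.72 to 1.29. Of 18 hypoxia and stress hormone genes, 3 were listed and higher in Chinese Simmental under every scaling, namely CEBPD at -3.77 ± 0.77 (-2.97 without Chinese Simmental replicate 3), VEGFA at -2.50 ± 0.60 and the metallothionein MT1E at -1.56 ± 0.60. The call for MT1E was lost without Angus replicates 2 or 3 or Chinese Simmental replicates 2 or 3, with values from -1.55 to -1.22.

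Genes of lipid metabolism, the subject of the study's title, appeared in small numbers and most were higher in Chinese Simmental, the breed in which the myeloid markers were also higher (10 of 10 listed, median log2 fold change -3.28), as were 75.0% of all listed genes. Against the other listed genes, neither tested lipid list was past the threshold (adjusted p = 0.931 by limma's camera for triacylglycerol synthesis and for adipogenesis regulators). Of 20 adipocyte markers 4 were listed, all higher in Chinese Simmental under every scaling. DGAT2, which catalyses the last step of triacylglycerol synthesis, was 12.0-fold higher at 55579 ± 27511 against 4634 ± 3362. CFD (adipsin) was 4.52-fold higher at 129757 ± 49385 against 28731 ± 14795, the transcription factor CEBPA 7.39-fold at 1384 ± 1056 against 187 ± 114, and the hormone-sensitive lipase LIPE 3.27-fold at 2112 ± 888 against 646 ± 275. The log2 fold change of DGAT2 went from -3.58 to -4.20 without Angus replicate 3, and that of CEBPA from -2.88 to -2.04 without Chinese Simmental replicate 3. Of 16 triacylglycerol synthesis genes 7 were listed, 5 of them higher in Chinese Simmental, such as GPAT3 at 7.29-fold, and 2 of these 5 turned with factors computed over the listed genes. GPAT4 was 1 of those 2, at -1.33 ± 0.35 with the authors' size factors. AGPAT2, an acyltransferase of the same pathway, was 3.04-fold higher in Angus at 2215 ± 163 against 728 ± 182.

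Of 17 lipolysis and lipid droplet genes 4 were listed and higher in Chinese Simmental, namely G0S2, LIPE, the droplet coat protein PLIN3 at -1.12 ± 0.40, which turned with factors computed over the listed genes, and the receptor ADRB3 at -1.50 ± 0.58. The call for PLIN3 was lost without Angus replicate 2 or 3, at -1.03 and -0.94, and that for ADRB3 without Angus replicates 2 or 3 or Chinese Simmental replicates 1 or 3, with values from -1.63 to -1.14. From the fatty acid synthesis list of 18 genes, PGD, a dehydrogenase of the pentose phosphate pathway, was 3.83-fold higher in Chinese Simmental. Fatty acid uptake and activation had 2 of 16 listed, ACSL6 at 10.5-fold and VLDLR at 8.83-fold higher in Chinese Simmental under every scaling. Of 17 PPAR and PGC-1 genes 3 were listed and higher in Chinese Simmental under every scaling, with RXRA at -1.93 ± 0.45, PPARD at -1.66 ± 0.38 and the liver X receptor NR1H3 at -1.38 ± 0.50. The NR1H3 call was lost without Angus replicates 2 or 3 or Chinese Simmental replicates 1 or 3, with values from -1.27 to -1.09. Of 21 adipogenesis regulators 7 were listed, with CEBPD at 13.6-fold and KLF4 at 6.98-fold among 5 higher in Chinese Simmental under every scaling, and EBF1 at 4.07-fold among 2 higher in Angus. Leaving out Angus replicate 3 moved the log2 fold change of VLDLR from -3.14 to -3.79. Leaving out Chinese Simmental replicate 3 moved those of G0S2, CEBPD and KLF4 from -6.67, -3.77 and -2.80 to -5.64, -2.97 and -2.19. Leaving out Angus replicate 1 moved that of KLF4 to -3.40. EBF1 is also a B cell transcription factor, and DGAT2, CFD and CEBPA are also expressed outside fat cells. Which cells carried G0S2, CEBPD, KLF4 and the other lipid genes was not tested. All 13 listed neutrophil genes, of a list chosen after the results were seen, were also higher in Chinese Simmental.

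Genes of muscle fibres were few and went both ways. Of 15 fast fibre sarcomere genes 3 were listed, with fast troponin TNNT3 4.82-fold higher in Angus at 938 ± 527 against 195 ± 141 and myosin binding protein MYBPC2 2.79-fold higher at 313 ± 69.6 against 112 ± 48.3. The MYBPC2 call was lost without Angus replicate 2, Chinese Simmental replicate 2 or Chinese Simmental replicate 3, at 1.30, 1.19 and 1.502. TPM1, which is also expressed outside muscle, was higher in Chinese Simmental at -1.36 ± 0.42, turned with TMM or RLE factors over the listed genes, and lost its call without Angus replicate 3 or Chinese Simmental replicate 3, at -1.21 and -0.97. The slow fibre list had 1 of 15 genes, ANKRD2, at 7.94-fold higher in Chinese Simmental. The log2 fold change of ANKRD2 went from -2.98 to -3.69 without Angus replicate 3, and that of TNNT3 from 2.27 to 3.05 without Chinese Simmental replicate 1. Of 20 myogenic regulators and growth genes 2 were listed, IGF1R at 6.33-fold higher in Chinese Simmental and ACVR2B at -1.35 ± 0.40. ACVR2B turned with TMM or RLE factors over the listed genes, and on log2(FPKM + 1) its difference was -0.30 and not past the threshold. All 9 listed of 21 muscle protein breakdown genes were higher in Chinese Simmental, as were the 10 listed myeloid markers (median log2 fold change -3.28). Of the 9 genes, 4 turned with factors computed over the listed genes. The list was not past the threshold against the other listed genes (adjusted p = 0.199 by limma's camera). The 9 included the calpain CAPN2 at 3.32-fold, the muscle calpain CAPN3 at 16.4-fold from 32.3 ± 21.0 to 531 ± 477 (log2 fold change -4.02, -4.71 without Angus replicate 1 and -3.10 without Chinese Simmental replicate 3), the lysosomal protease CTSB, which is not specific to muscle, at 3.51-fold and 70195 ± 25411 against 19992 ± 4614, and the ubiquitin ligase FBXO32 at only 3.33 ± 1.38 against 26.9 ± 6.56, with counts shared with another listed name.

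Glycolysis and glycogen genes were higher in Chinese Simmental at 6 listed of 22 (adjusted p = 0.346 by limma's camera), as were the 10 listed myeloid markers (median log2 fold change -3.28). Among the 6 were PKM at 3.38-fold, the glycogen synthase GYS1 at 3.21-fold and PFKFB3, a regulator of phosphofructokinase, at 4.26-fold. ALDOA was at -1.25 ± 0.41, was the 1 member that turned with factors computed over the listed genes, and lost its call without any of the Angus replicates, with values from -1.27 to -1.24. Of 53 nuclear-encoded oxidative phosphorylation genes 1 was listed, the striated muscle subunit COX6A2, 4.33-fold higher in Angus at 142 ± 74.8 against 32.7 ± 17.0, a call lost without Angus replicate 1 at 1.63. Transcripts of the mitochondrial genome were higher in Angus in the authors' deposited table, at 4 listed of 26 genes in 2 distinct loci. COX1 stood at 2438212 ± 423754 in Angus against 615691 ± 542698 in Chinese Simmental and was not past the threshold, with a log2 fold change of 1.99 ± 0.89 and an edgeR quasi-likelihood Benjamini-Hochberg adjusted p of 0.0512. It was past the threshold in 12 of 18 alternatives, at 1.45 to 3.60, among them DESeq2, limma-trend, the replicate block at 2.67, and the fits without Chinese Simmental replicate 1 or 3, at 1.45 and 2.80. The 12 also include TMM, RLE and upper quartile factors over the listed genes, which by construction move fold changes toward Angus. The locus of ATP6, ATP8 and COX3, whose names share 1 set of counts, was at 2.17 ± 0.95 with an edgeR quasi-likelihood adjusted p of 0.0471, and lost its call without any Angus replicate or without Chinese Simmental replicate 2, with values from 1.998 to 2.41, and stood at 2.91 without Chinese Simmental replicate 3. COX1 held 15.4% to 18.5% of the listed counts in Angus libraries, 3.15% and 4.08% in Chinese Simmental replicates 2 and 3, and 0.454% in Chinese Simmental replicate 1.

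Matrix remodelling enzymes were higher in Chinese Simmental under every scaling at 5 listed of 18 (adjusted p = 0.272 by limma's camera), as were the 10 listed myeloid markers (median log2 fold change -3.28). The gelatinase MMP9, which neutrophils also make, was at 18.4-fold and 3259 ± 3526 against 177 ± 96.4, the procollagen protease ADAMTS2 at 10.1-fold, MMP19 at 5.32-fold and TIMP2 at 3.83-fold. MMP9 stood at 445.8, 2115.1 and 7215 in Chinese Simmental replicates 1 to 3, and its log2 fold change went from -4.21 to -2.86 without replicate 3. Those of ADAMTS2 and MMP19 went from -3.34 and -2.41 to -4.05 and -3.19 without Angus replicate 1. Of 26 collagen and matrix genes 3 were listed. Elastin (ELN) was 7.18-fold higher in Chinese Simmental at 9588 ± 1300 against 1336 ± 428, and the basement membrane collagen COL4A2 was 3.28-fold higher in Angus. TNXB was higher in Angus at 1.22 ± 0.39, a call lost without Angus replicate 2 at 1.09. Among 3 listed of 16 fibroblast and progenitor markers, THY1 (log2 fold change -5.48, and -3.86 and -6.32 without Chinese Simmental replicate 3 and Angus replicate 2) and GSN, at 3.13-fold, were higher in Chinese Simmental under every scaling. PDGFRA, the receptor that marks fibro-adipogenic progenitors, was higher in Angus at 1.84 ± 0.70, with Angus replicate 1 at 1023 and the other Angus libraries at 245 and 225, and its difference was 0.76 and not past the threshold without that library. The PDGFRA call was also lost without Chinese Simmental replicate 1 or 2, at 1.83 and 1.54, and on log2(FPKM + 1), at 1.08. Of the endothelial markers 1 of 17 was listed, VWF, which platelets also hold, at 3.68-fold higher in Chinese Simmental with overlapping breeds.

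Single members stood for a few other lists, each higher in Chinese Simmental, as were the 10 listed myeloid markers. IRS2, an insulin receptor substrate and the 1 listed of 23 insulin and AMPK signalling genes, was at -2.66 ± 0.71, and at -1.80 without Chinese Simmental replicate 3. MBP, the 1 listed of 10 Schwann cell and nerve markers and a gene with a transcript form in leukocytes, was at -1.17 ± 0.43, and BUB1, a mitotic checkpoint kinase and the 1 listed of 20 replication and mitosis genes, at -1.19 ± 0.42. Both MBP and BUB1 turned with factors computed over the listed genes. MBP lost its call without Angus replicates 1 or 2 or Chinese Simmental replicates 2 or 3, with values from -1.18 to -0.91, and BUB1 without Angus replicates 1 or 3 or Chinese Simmental replicate 3, with values from -1.16 to -1.002. No gene was listed from 7 lists, which were mitochondrial fatty acid oxidation (20 genes), cholesterol synthesis (18), the citric acid cycle (19), smooth muscle and pericyte markers (12), red cell markers (10), the circadian clock (19) and cytosolic ribosomal proteins (74). The 12 genes chosen in advance to be named whatever their values, ADIPOQ, FABP4, PLIN1, LPL, FASN, SCD, PPARG, CPT1B, MSTN, MYH7, MYH1 and HBB, were not among the listed genes either, so their levels were not analysed here.

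**Figure D3:**
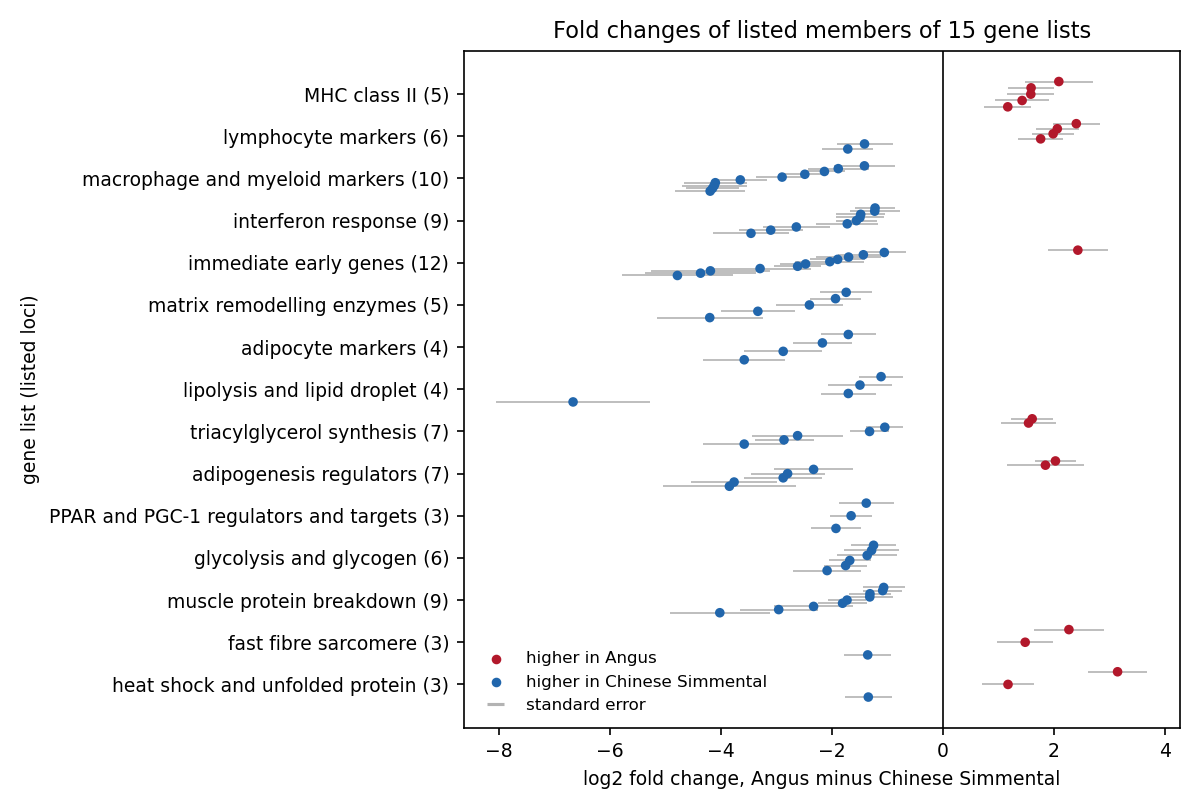
Log2 fold change, Angus minus Chinese Simmental, with its standard error, of each listed locus in 15 gene lists, with the number of loci in brackets and the vertical line at 0. The 5 listed loci of the fixed MHC class II list lie to the right (higher in Angus). The 10 myeloid loci all lie to the left, under every scaling, while values between -1.36 and 0 include loci that turn with factors computed over the listed genes.

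Of the lists, 10 had at least 5 listed loci and were tested with camera against the other listed genes, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 10. MHC class II (median log2 fold change 1.58, adjusted p = 0.00417 by limma's camera) and lymphocyte markers (1.87, adjusted p = 0.0211) stood toward Angus, and myeloid markers (-3.28, adjusted p = 0.0211) toward Chinese Simmental. At the preset correlation, 5 of the 10 splits of the libraries into 3 and 3, the real one included, gave at least 3 lists past the threshold. None of the 3 calls held with an estimated correlation, where limma's camera gave adjusted p = 0.226 for MHC class II, adjusted p = 0.618 for lymphocyte markers and adjusted p = 0.740 for myeloid markers. The lymphocyte call was also lost with TMM, RLE or upper quartile factors over the listed genes (adjusted p = 0.0512, 0.0554 and 0.0512 by limma's camera), and the myeloid call without Chinese Simmental replicate 1 (adjusted p = 0.0857). The lists not past the threshold in limma's camera had adjusted p of 0.199 for interferon response and for muscle protein breakdown, 0.272 for matrix remodelling, 0.346 for immediate early genes and for glycolysis, and 0.931 for triacylglycerol synthesis and for adipogenesis. The last pair had negative medians (-1.33 and -2.80) and means (-1.19 and -1.68) and a camera direction toward Angus, since camera compares them with other listed genes, which are mostly higher in Chinese Simmental. In each list the number of loci past the threshold adjusted over the list alone equalled that over all genes tested, except for the mitochondrial genome (0 against 1), and since the authors chose the genes on these samples, neither count is independent evidence.

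The authors' deposited table gave the same direction as the group means for all 2040 genes. Its fold change was smaller than the ratio of the group means for all 2003 genes with reads in both breeds. For CD163 the authors' deposited table gave a log2 fold change of -3.97 with an adjusted p of 5.9e-25, and for CD79B 2.32 with 2.25e-11. For DGAT2 the authors' deposited table gave -3.18 with 2.42e-07, and for DUSP1 -4.01 with 1.51e-08. Of the 1989 genes tested with edgeR here, COX1 and BBS5 were not past the threshold, and BBS5, a gene of the primary cilium named after its value was seen, had an adjusted p of 0.0526 in the quasi-likelihood test.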

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

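The authors' size factors of the main fit were chosen after seeing the data, in place of the TMM factors named by the design. Totals implied by FPKM, limma on FPKM, Fisher's exact test of direction, upper quartile factors for the lists and FPKM for the correlation between libraries were also chosen after seeing the data. The other alternatives were chosen before. The number of genes higher in Angus (495) stayed between 374 and 509 under every alternative except leaving out 1 library, where it ran from 291 (without Angus replicate 2) to 466. The 1492 genes higher in Chinese Simmental became 263 with RLE, 282 with upper quartile and 256 with TMM factors over the listed genes, and ran from 1059 to 1423 without 1 library and from 1189 to 1531 elsewhere. These factors centre a list of genes that is mostly higher in Chinese Simmental, which by construction moves the fold changes toward Angus, and the share of calls higher in Angus went from 24.9% to 65.7%, 64.1% and 66.3%. Totals implied by FPKM moved them by 0.07. Under RLE, upper quartile and TMM factors, 7, 5 and 7 of 92 named genes turned. The log2 fold changes became 0.0528, 0.0071 and 0.0448 for GPAT4, 0.17, 0.15 and 0.19 for PLIN3, 0.16, 0.11 and 0.16 for ALDOA, 0.23, 0.18 and 0.23 for MBP and 0.14, 0.10 and 0.14 for BUB1, and with RLE and TMM 0.0328 and 0.0420 for TPM1 and 0.0094 and 0.0150 for ACVR2B. Another 26, 28 and 26 lost their call. The 3 lists past the threshold became 0 with an estimated correlation, 9 with fry, which tests a set on its own, and 1 with Fisher's exact test of direction, and ran from 2 to 3 without 1 library. With the replicate block, 473 and 1464 genes and 3 lists were past the threshold, and among the 92 named genes COX1 gained its call and no other call changed. The largest correlation between breeds was 0.893 on counts and 0.898 on FPKM. Depth limits low genes, since a minimum count of 100 left 1688 genes for testing, 81 of them among the 92 named. KCTD19 was filtered out with RLE factors and has no value there.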

Other observations

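The lists of blood cell genes and of muscle fibre genes, the annotation terms and all tests of explanations below were chosen after the results were seen. Of 24 B cell genes, 18 distinct loci were listed and all 18 were higher in Angus, with a median log2 fold change of 1.98. SPIB, a transcription factor of B and plasmacytoid cells, stood at 47003 ± 10323 in Angus against 9777 ± 1993 in Chinese Simmental, and PAX5, which fixes B cell identity, at 15004 ± 1899 against 3792 ± 839 (SD over 3 libraries). Of 24 T cell genes, 0 were listed. All 16 listed of 20 monocyte genes and all 13 listed of 20 neutrophil genes were higher in Chinese Simmental, with medians of -2.60 and -4.06, and factors computed over the listed genes turned 1 of the monocyte genes and up to 2 of the neutrophil genes. LYZ was 18.4-fold (log2 fold change -4.20, and -3.61 without Chinese Simmental replicate 3), FCN1 8.98-fold, S100A12 8.82-fold and IL1R2 27.9-fold higher in Chinese Simmental. The 8 listed of 20 natural killer and cytotoxic genes (median -1.57, 2 of them turned by those factors) and the 3 listed of 16 platelet genes, such as F13A1 at 6.60-fold, were higher in Chinese Simmental. The 11 listed of 58 muscle fibre genes went both ways, with 5 higher in Angus (6 with factors over the listed genes), such as NEB at 1143 ± 743 against 315 ± 88.2 (1.86, and 1.19 without Angus replicate 1), and RYR1 at 2566 ± 1528 in Chinese Simmental against 263 ± 136 (-3.28, and -2.69 without Chinese Simmental replicate 2). Among these 5 tested lists, limma's camera gave adjusted p = 1.81e-12 for B cell, 0.00446 for monocyte, 0.0122 for neutrophil, 0.325 for natural killer and 0.250 for muscle fibre genes. With an estimated correlation limma's camera gave adjusted p = 0.327 for B cell genes and adjusted p = 0.457 for monocyte and for neutrophil genes.

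Of 252 annotation terms with at least 10 listed loci, 4 differed in direction from the other listed loci by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment. That test counts loci as independent, though genes measured in the same libraries can vary together, so its adjusted p-values can be too small. Of all 1705 annotated loci, 24.2% were higher in Angus. Calcium ion binding leaned to Chinese Simmental, with 8 of 90 loci higher in Angus (adjusted p = 0.0195), and the other 82 included S100A8, S100A9, S100A12, the versican gene VCAN at -3.81 ± 0.53 and the dysferlin gene DYSF. The MHC class II protein complex leaned to Angus, with 8 of 10 loci higher there (adjusted p = 0.0195). Metal ion binding (53 of 125 higher in Angus, adjusted p = 0.000886) and nucleic acid binding (29 of 65, adjusted p = 0.0195) had larger shares higher in Angus than the other loci, though most of their loci, 72 and 36, were higher in Chinese Simmental. The COX1 share of listed counts, given per library with the mitochondrial genes, was lowest in Chinese Simmental replicate 1.

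Listed leukocyte transcripts exceeded listed muscle fibre transcripts, by medians, in all 6 libraries labelled longissimus dorsi. All genes concerned had been picked by the authors from these libraries for differing between breeds, and 5 of the 18 B cell loci, 10 of the 10 myeloid loci and 8 of the 11 muscle fibre loci are also in another list used here. The highest ratio of the muscle fibre median to the higher of the B cell and myeloid medians was 0.0313 over the 6 libraries in normalized counts and FPKM, and the lowest ratio of a leukocyte median to the muscle fibre median was 3.70. These ratios rest on 11 listed of 58 fibre genes, whose median was 1.63 to 7.17 FPKM over the 6 libraries. For these genes, medians this far below the leukocyte medians in every library argue against RNA mostly from muscle fibres with a small share of blood cells. The levels of unlisted fibre genes are unknown here, so this covers the listed genes only. The source of the RNA as a whole stays undecided, since most fibre genes were not listed. RNA mostly from blood or lymphoid cells cannot be told apart here from a mixed or mislabelled sample.

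B cell genes were higher in Angus while myeloid genes were higher in Chinese Simmental. The authors' scaling cannot move the log2 ratio of B cell genes to myeloid markers within a library. That ratio was 1.72 ± 0.68 in Angus and -3.32 ± 0.65 in Chinese Simmental (SD over 3 libraries), a difference of 5.04. Scaling therefore cannot account for the difference between the sets, but the ratio does not show which set differs. All these loci had passed the authors' selection on fold change, so a difference between the sets was fixed by that choice. For the B cell genes, a single change in the share of B cells is a candidate explanation that was not decided. The SD of their log2 fold changes was 0.798 times their median standard error. Spread between libraries that these genes share enters the standard error but not that SD, and the authors' selection on fold change narrows that SD. For the myeloid markers the SD was 2.10 times the median standard error (95% interval 1.44 to 3.83). That does not decide whether 1 myeloid cell type changed its share, with some of its markers also made by other cells, or several types or their expression changed. A breed difference in leukocyte makeup or tissue sampling is confounded with the groups and was not tested.

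Immediate early genes were higher in Chinese Simmental, at 11 of 12 listed loci. A higher share of myeloid cells could carry them, but the log2 ratio of immediate early genes to myeloid markers within a library was -1.14 ± 0.20 in Angus and -2.27 ± 0.79 in Chinese Simmental (SD over 3 libraries), a difference of 1.13 that is under 2 times the larger SD and does not decide. Handling between slaughter and freezing may also move such genes, and their median varied 3.11-fold between Chinese Simmental libraries against 1.398-fold for the myeloid markers, and 2.46-fold against 2.30-fold between Angus libraries, but the labels give no handling times, so handling and breed cannot be told apart. The breed difference itself was not tested apart from these.

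The 6 libraries can be split into 3 and 3 in 10 ways, which is too few for a share under 0.05. These splits ignored the replicate numbers. The real split gave 1987 genes past the threshold and the highest other split 3, so 1 of the 10 splits gave as many, on genes chosen for the real split. For the gene lists, the real split gave 3 lists past the threshold and 5 of the 10 splits gave as many, with 4 in the highest other split.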
